A study of Danio rerio with 8 samples.

How the data were processed

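Polyadenylated RNA from whole zebrafish larvae at 5 days post fertilization was sequenced in 8 samples, 4 labelled as *seph* mutant and 4 as wild type. The deposited table holds whole-number read counts per Ensembl gene, with 1 column per sample. Per the submitters' processing notes, STAR 2.3.0e and HTSeq 0.6.0 were used. The genome build, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The columns sum to different totals and hold no fractions, so the deposited counts were analysed as raw. No column of another sample was present.

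The table lists 32434 genes, of which 226 have 0 counts in every library. Totals ran from 51246749 to 56409917 counts per library. At this depth 3 counts, the most that a count of 0 allows, correspond to between 0.053 and 0.059 CPM. Intervals and such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Among genes with counts above 0, 1634 have exactly the same 8 values as another gene, 715 of them with at least 20 counts, which can arise where reads were counted for more than 1 annotated gene. Values of near-identical paralogs are therefore uncertain, as are those of overlapping or antisense genes. The 13 mitochondrially encoded genes have 0 counts in all libraries, so that list was not tested.

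Gene symbols came from a table pairing Ensembl IDs with symbols, which named 20769 of the IDs, and are written here in lower case. Some symbols belong to more than 1 ID, and the ID is then given. Of 1421 entries in the 39 gene lists, 889 matched by symbol, 174 by a synonym in the GRCz12tu gene table, 123 by a symbol without its final a or b, and 235 were not matched. One entry, rela, was kept out of that last matching step because it led to another gene. The lists, the groups, the tests, the rule for named genes and most alternatives were fixed before the data were examined.

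Genes were filtered with filterByExpr (minimum count 10), which left 27050 genes, 19181 of them with a symbol. Counts were scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with genotype as the only term and Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 are called changed. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM values are TMM scaled, and SD and n refer to the 4 libraries of a group. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over 38 lists. Estimated correlations and fry were alternatives. The level of *selenoh* was compared with an exact two-sided permutation test over the 70 arrangements of 4 and 4 libraries, whose smallest p is 0.0286. Called genes on the chromosome of *selenoh* were compared with Fisher's exact test, two-sided, using chromosome names of GRCz12tu for 13454 tested genes.

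The genes named below are *selenoh*, the 10 largest increases and 10 largest decreases among called genes with a mean of at least 5 CPM, non-overlapping groups and a symbol that is not a clone name, up to 4 called members per list with the smallest p, up to 2 members where a list had no called one, and, from a set always named, mdm2, cdkn1a, gpx1a, gclc, hmox1a and il1b. The clone prefixes of this rule were applied only where digits followed, so that names such as ctrb stayed in. il1b was not matched to an ID and is not analysed here. Some genes that the rule names are not reported here. Genes outside the rule that the closing section names were chosen after their values were seen.

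The labels do not say that the samples of a group came from separate clutches, so p-values measure only the spread between these samples, which may be technical. Wild type replicates 1 and 2 were the closest pair, with a mean squared difference of 4.97 in units of counting noise against 14.6 to 52.1 for the other pairs within a group. They differed by more than counting noise, which argues against the same library deposited again but does not show separate RNA samples. They were counted as separate samples, as labelled.

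The alternatives were DESeq2 size factors, upper-quartile factors, library size only, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, other expression filters, a replicate block, 1 surrogate variable from sva 3.50.0, stricter thresholds and leaving out each library. Leaving out both replicate 3 libraries, a term for them, TMM factors without the exocrine list and removal of genes with identical values were added after the data were seen. The steps were tested on simulated counts for the 27050 genes, drawn with the means, dispersions and library sizes of the *seph* mutant against wild type comparison. edgeR recovered 1 of 67 genes changed 1.5-fold, 25 of 67 changed 2-fold and 62 of 66 changed 4-fold, with 5 false calls. The DESeq2 Wald test recovered 15, 44 and 64 of them, with 60 false calls among 193 calls in all, a larger false share than that of edgeR. In the simulation edgeR made 97 calls in all, against 4626 in the data. Its adjusted threshold was therefore stricter there, and these shares can understate recovery in the data. camera called a planted list of 30 genes changed 1.5-fold and 0 of 37 unchanged lists. The simulated genes were drawn independently, so this does not test camera on lists whose genes vary together. In the data the estimated correlation reached 0.93, for ribosomal proteins.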

Results

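Zebrafish larvae carrying a mutation in *seph*, the gene of the selenium-containing nuclear protein selenoprotein H (now named *selenoh*), were compared with wild type larvae at 5 days post fertilization. Each group had 4 libraries of polyadenylated RNA. Wild type replicates 1 to 4 held 55696250, 56409917, 53865807 and 51246749 counts, and mutant replicates 1 to 4 held 53413616, 54669490, 55273388 and 53153770. The group means were 54304681 ± 2303044 and 54127566 ± 1010708 counts (SD, n = 4 each). The series title places the gene in redox control and in cooperation with p53, and the comparison asks which transcripts differ when it is mutated.

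*selenoh* (ENSDARG00000093022) was almost undetected in the mutant. Wild type libraries had 854, 855, 1225 and 737 counts, and mutant libraries had 1, 20, 0 and 0, where a count of 0 allows up to 3 counts. The mean level was 0.0939 ± 0.176 CPM in the mutant and 17.3 ± 3.39 CPM in wild type (SD, n = 4 each), or 0.543% of wild type (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). Every mutant library lay below every wild type library, so each library matched its label. Without mutant replicate 2, the only mutant library with more than 1 count, the level was 0.0348% of wild type. An unnamed gene, ENSDARG00000059124, had the same counts in all 8 libraries, so the reads of the pair cannot be separated.

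Genes differed between mutant and wild type in both directions, and digestive enzyme genes were among the largest decreases. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 2339 genes rose and 2287 fell among 27050 tested. Of these, 718 rose and 816 fell at least 2-fold. The largest increases were in jac9 (log2 fold change 5.56 ± 0.36, SE) and jac8 (4.96 ± 0.44), followed by the chemokine cxcl18b (3.86 ± 0.40), plac8 (ENSDARG00000094438, 3.75 ± 0.58), tnfaip2b (3.62 ± 0.37), irg1l (3.60 ± 0.61), the complement component c4b (3.48 ± 0.35), the leptin gene lepb (3.29 ± 0.96), the mitochondrial folate enzyme mthfd1l (2.71 ± 0.45) and the p53 inhibitor mdm2 (2.70 ± 0.16). The largest decreases were in the astacin protease genes c6ast4 (-8.83 ± 0.50) and c6ast3 (-8.57 ± 0.52), the elastase gene ela2 (-8.44 ± 0.39), the amylase gene amy2a (-8.35 ± 0.37) and the chymotrypsinogen gene ctrb.2 (-8.16 ± 0.35), then cela1.3 (-8.03 ± 0.86), the lipase gene cel (ENSDARG00000029822, -7.76 ± 0.39), ela2l (-7.65 ± 0.49), the trypsin gene prss59.1 (-7.61 ± 0.44) and *selenoh* itself (-7.48 ± 0.73). The groups did not overlap for 5970 tested genes, 22.1% of them, where chance gives 2.86%. Scaling by library size only gave 2713 higher and 1647 lower, or 62.2% higher against 50.6%. Leaving out 1 library gave between 1262 higher and 1235 lower (without wild type replicate 2) and 3667 higher and 3374 lower (without wild type replicate 3), with 1465 and 1329 without mutant replicate 1, 1486 and 1357 without mutant replicate 2, 1292 and 1294 without wild type replicate 1, and 4200 and 3956 without both replicate 3 libraries. Of the genes named here, lepb alone lost its call with 1 library left out, which was any except mutant replicate 3 and wild type replicate 4 (edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.0553 to 0.126 in those 6 fits, 0.00358 to 0.126 over all its alternatives).

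**Figure D1:**
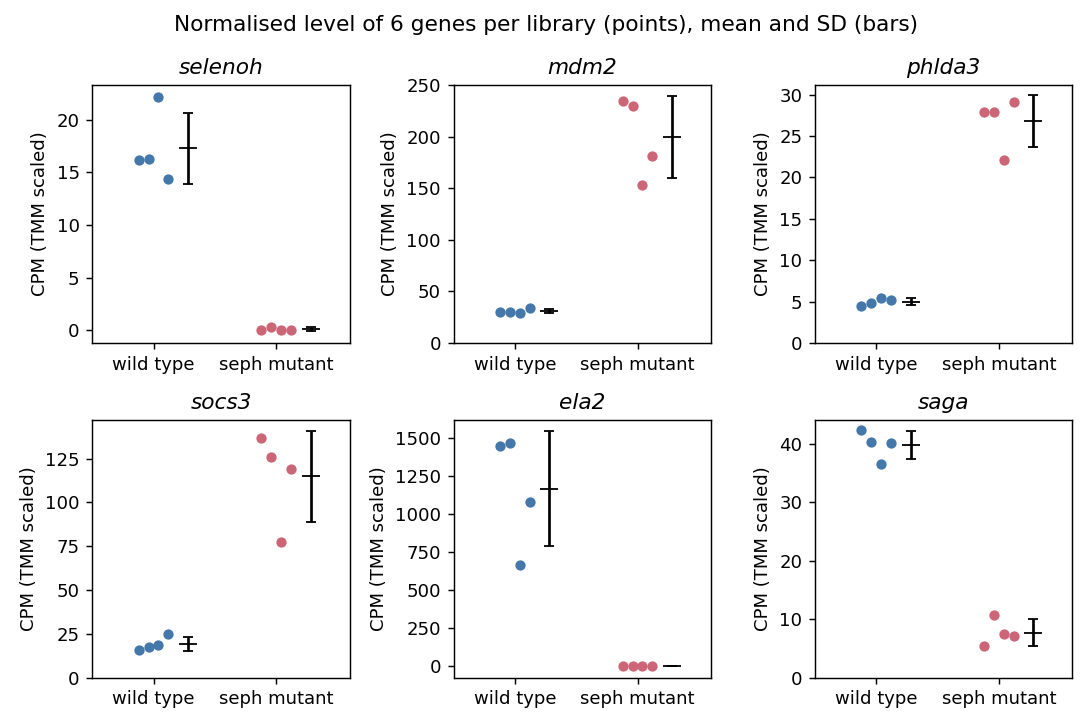
TMM-scaled CPM of 6 genes in each library (points) with the mean and SD of the 4 libraries of each group (bars). *selenoh*, ela2 and saga were lower in every mutant library than in any wild type library, and mdm2, phlda3 and socs3 (ENSDARG00000026611) were higher.

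Both replicate 3 libraries stood apart from the other 6. The first principal component, 43.6% of the variance, separated the genotypes. The second, 20.5%, put mutant replicate 3 at -59.6 and wild type replicate 3 at -71, against 15.7 to 27.4 for the others. In these libraries the circadian clock list deviated most from the other libraries of the same group, by a median of 1.16 on the log2 scale, followed by cholesterol synthesis (1.15), glucocorticoid response (1.06) and cell cycle genes (0.93).

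**Figure D2:**
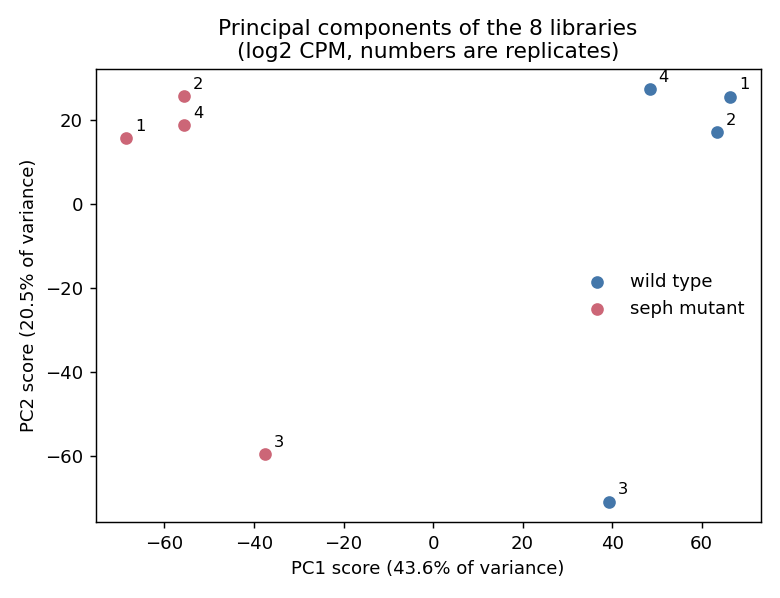
Scores of the 8 libraries on the first and second principal components of log2 CPM, with replicate numbers beside the points. The genotypes separate along the horizontal axis and both replicate 3 libraries lie at the bottom, at -59.6 and -71.

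Of 38 gene lists fixed beforehand, camera called 17, of which 8 rose and 9 fell. With an estimated correlation between genes only the exocrine pancreas and p53 target lists kept their calls, with adjusted p = 0.0143 and 0.0455. With fry, which tests whether a list's genes move one way and does not compare them with other genes, the epidermis (adjusted p = 0.0695) and erythroid lists (0.139) lost their calls, and the neutrophil (0.0139), pigment cell (0.0376) and glia lists (0.00294) gained one. The counts of members below refer to all genes tested unless stated. In the 8 fits that left out 1 library, 7 of the 38 lists (inflammation, exocrine pancreas, neutrophil, lymphoid, photoreceptor, glia and endocrine pancreas) kept both counts within 1.5 times those given. Adjusted over the list alone, the counts equalled those over all genes in the lists of p53 targets, Nrf2, selenium incorporation, DNA damage, heat shock, oxidative phosphorylation, cholesterol, fatty acids, glucocorticoid response, exocrine pancreas, erythroid, cartilage and ionocytes.

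**Figure D3:**
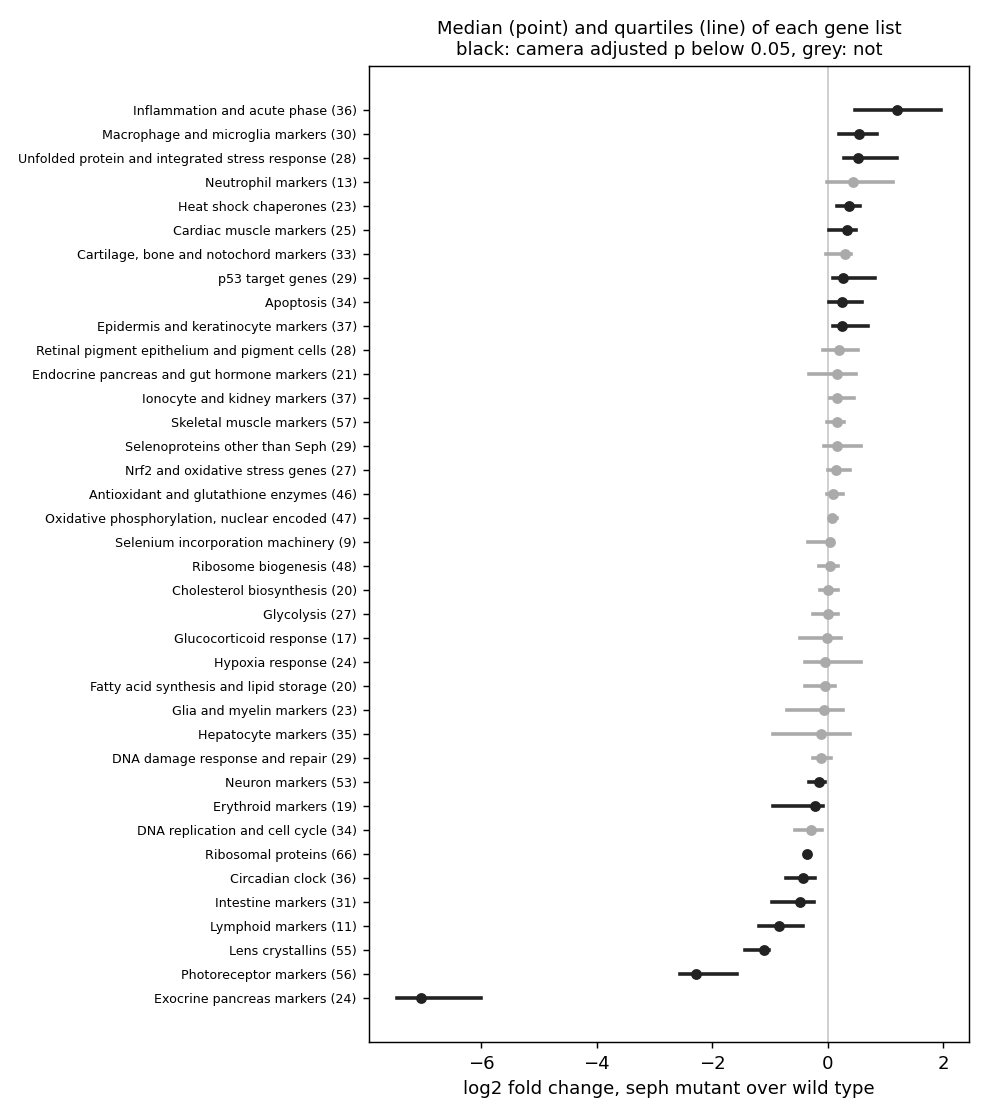
Median and quartiles of the log2 fold changes of each list's tested members (numbers in brackets), with black for camera adjusted p under 0.05. The exocrine pancreas list lies lowest, at -7.04, and the inflammation list highest, at 1.199.

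Exocrine pancreas genes fell as a group. Of 24 measured members 23 fell, with a median log2 fold change of -7.04, about 132-fold, and the count adjusted over the list alone was also 23 (camera adjusted p = 7.36e-144). Together they took 2.59% ± 0.884 of wild type counts and 0.0196% ± 0.00626 of mutant counts (SD, n = 4 each, exact permutation p = 0.0286). The carboxypeptidase gene cpa1 (ENSDARG00000030915), with the smallest p of all genes, fell from 119 ± 15.3 to 0.695 ± 0.281 CPM (SD, n = 4 each). Other digestive organs moved far less. Of 31 intestine genes 12 fell and 3 rose (median -0.48, camera adjusted p = 0.00016, adjusted p = 0.115 with an estimated correlation). They included the fatty acid binding protein fabp2 (-1.47 ± 0.23) and the chitinase chia.3 (-1.22 ± 0.15), while the endocytic adaptor dab2 (ENSDARG00000053091) rose by 0.79 ± 0.12. Leaving out mutant replicate 1 or 2 or wild type replicate 1, 2 or 4 left 1 intestine gene higher, and leaving out wild type replicate 3 gave 5. In the intestine list 15 fell and 3 rose adjusted over the list alone. Among 35 hepatocyte genes 9 fell and 4 rose, and the list was not called (median -0.12, camera adjusted p = 0.3). The urate oxidase uox fell by 1.56 ± 0.22, and the fibrinogen genes fgb and fgg rose by 1.03 ± 0.17 and 0.88 ± 0.14. Without wild type replicate 3, 7 hepatocyte genes rose. Adjusted over the list alone, 10 hepatocyte genes fell and 6 rose, and 5 endocrine genes rose and 5 fell. The endocrine pancreas and gut hormone list was not called either (4 of 21 rose, 3 fell, median 0.17, camera adjusted p = 0.814). Its members pyya (0.70 ± 0.10), isl1 (-0.90 ± 0.12), neurod1 (-1.92 ± 0.31) and pax6 (-1.13 ± 0.17) went both ways, and the last 3 also act in the nervous system.

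Genes of the p53 response rose as a list. Of 29 p53 target genes 10 rose, and also 10 adjusted over the list alone (median 0.27, camera adjusted p = 3.65e-09, adjusted p = 0.0455 with an estimated correlation), and 6 rose without wild type replicate 1 or 2. Among them mdm2 rose from 30.7 ± 2.14 to 200 ± 39.7 CPM (SD, n = 4 each). The Akt inhibitor phlda3 rose by 2.43 ± 0.12 on the log2 scale and the cyclin ccng1 by 1.53 ± 0.15. In contrast, the cell cycle inhibitor cdkn1a was not called (1.27 ± 0.65, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.216). Its level in the replicate 3 libraries was low in both groups, 35.9 CPM in the mutant and 4.24 CPM in wild type. Without both replicate 3 libraries it rose by 1.16 (adjusted p = 0.00288 by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, lowest to highest 0.00288 to 0.369 over its alternatives). Of 34 apoptosis genes 8 rose and 2 fell (median 0.25, camera adjusted p = 0.0059, adjusted p = 0.16 with an estimated correlation), among them the death receptor tnfrsf1a (1.71 ± 0.16), the initiator caspase casp8 (1.87 ± 0.22) and baxb (1.04 ± 0.22). The 8 became 5 without mutant replicate 2 or 4 or wild type replicate 2, and 4 without wild type replicate 1. The 2 became 0 without mutant replicate 1 or 2 or wild type replicate 1, and 1 without wild type replicate 2. For apoptosis 10 rose and 3 fell adjusted over the list alone. This list shares 5 tested genes with the p53 target list. The DNA damage response and repair list was not called (2 of 29 rose, 1 fell, median -0.12, camera adjusted p = 0.82). Its risen members were parp3 (1.75 ± 0.12) and the Fanconi anaemia gene fancd2 (0.48 ± 0.10), and without wild type replicate 3 the median was 0.11 and 7 rose.

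Photoreceptor and lens genes fell as lists. Of 56 photoreceptor genes 42 fell (median -2.28, 49 adjusted over the list alone, camera adjusted p = 3.46e-40, adjusted p = 0.104 with an estimated correlation). The arrestin gene saga fell from 39.8 ± 2.43 to 7.67 ± 2.29 CPM (SD, n = 4 each). The phosphodiesterase subunit pde6b (ENSDARG00000011671, -2.59 ± 0.30) fell, as did both copies of the channel gene cnga1, ENSDARG00000012125 (-2.03 ± 0.17) and ENSDARG00000029898 (-2.38 ± 0.22). Of 55 lens crystallin genes 43 fell (median -1.11, camera adjusted p = 1.31e-23, adjusted p = 0.313 with an estimated correlation), including grifin (-3.27 ± 0.36) and cryaa (-2.37 ± 0.33). The lens count was 27 without mutant replicate 2, 28 without mutant replicate 4, 24 without wild type replicate 1 and 23 without wild type replicate 2. Of the lens genes 49 fell and 1 rose adjusted over the list alone. Against the other libraries of their groups, lens genes deviated by a median log2 of 0.957 in mutant replicate 3 and -0.436 in wild type replicate 3. Only 3.64% of them deviated in the same sense in both, so the lens difference was smaller between the replicate 3 libraries. The list of retinal pigment epithelium and pigment cells was not called (7 of 28 rose, 3 fell, median 0.20, camera adjusted p = 0.14). There 3 rose without mutant replicate 1 or 2 or wild type replicate 1 or 2, and 4 without mutant replicate 4, while 1 fell without mutant replicate 4 or wild type replicate 1 or 2. Adjusted over the list alone, 9 pigment cell genes rose and 3 fell, 16 neuron genes fell and 4 rose, and 9 glia genes fell and 6 rose. Of 53 neuron genes 10 fell and 4 rose, with a median of -0.15 (camera adjusted p = 2e-04, adjusted p = 0.504 with an estimated correlation). The pump subunit atp1b2 (-1.15 ± 0.11), the glutamate transporter slc17a7 (ENSDARG00000090106, -1.07 ± 0.13) and the neurofilament gene ina (ENSDARG00000011862, -1.86 ± 0.26) fell. The 4 higher neuron genes became 0 without mutant replicate 2 or wild type replicate 1, 1 without mutant replicate 1 or wild type replicate 2 or 4, and 2 without mutant replicate 4. Glia and myelin genes went both ways (3 of 23 rose, 8 fell, camera adjusted p = 0.13): the Notch target her4.1 (-1.37 ± 0.10) and the myelin genes mpz (-0.82 ± 0.12) and mbpa (-0.69 ± 0.11) fell, and the glutamate transporter slc1a3 rose by 1.43 ± 0.13.

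Inflammatory genes rose. Of 36 genes of inflammation and the acute phase 18 rose (median 1.199, 20 adjusted over the list alone, camera adjusted p = 2.89e-14, adjusted p = 0.15 with an estimated correlation). The cytokine signal inhibitor socs3 (ENSDARG00000026611) rose from 19.2 ± 3.92 to 115 ± 26.1 CPM (SD, n = 4 each) and its activator stat3 rose by 1.22 ± 0.12. Of 30 macrophage and microglia genes 8 rose and 2 fell (median 0.54, camera adjusted p = 0.00062, adjusted p = 0.28 with an estimated correlation), with the scavenger receptor marco (1.56 ± 0.20), the transcription factor irf8 (1.54 ± 0.22) and the apolipoprotein apoeb (1.43 ± 0.22) higher. Only 1 macrophage gene fell without mutant replicate 1, 2 or 4 or wild type replicate 2, 3 or 4. Adjusted over the list alone, 10 macrophage genes rose and 3 fell, and 5 neutrophil genes rose and 2 fell. The neutrophil list was not called (4 of 13 rose, 2 fell, camera adjusted p = 0.0948), but passed as higher without wild type replicate 4 (0.00161, 0.00161 to 0.459 over its alternatives). adam8a rose by 2.04 ± 0.18 and the lysozyme gene lyz fell by 2.59 ± 0.28. Of 11 lymphoid genes 4 fell (median -0.84, 8 adjusted over the list alone, camera adjusted p = 8.89e-05, adjusted p = 0.104 with an estimated correlation). They included the recombinase gene rag1 (-2.88 ± 0.23), ikzf1 (-1.32 ± 0.20) and il7r (-1.50 ± 0.27).

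Genes of the unfolded protein and integrated stress response rose as a list. Of 28 members 13 rose (median 0.53, 17 adjusted over the list alone, camera adjusted p = 2.44e-09, adjusted p = 0.129 with an estimated correlation). The disulfide isomerase pdia4 rose by 1.72 ± 0.22, the co-chaperone dnajb9 (ENSDARG00000016886) by 1.46 ± 0.18 and the chaperone hsp90b1 by 1.37 ± 0.20. Of 23 heat shock chaperone genes 5 rose and 1 fell (median 0.37, camera adjusted p = 0.00636, adjusted p = 0.504 with an estimated correlation). The collagen chaperone serpinh1 (ENSDARG00000075954) rose by 1.499 ± 0.105 and hspb1 by 0.90 ± 0.13, and 3 members of this list fell without wild type replicate 3.

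Lists of redox and selenium genes were not called with all 8 libraries. The antioxidant list shares 9 tested genes with the Nrf2 list and 9 with the selenoprotein list, so their results are not independent. The list of Nrf2 and oxidative stress genes was not called (2 of 27 rose, 3 fell, median 0.14, camera adjusted p = 0.409), nor was that of antioxidant and glutathione enzymes (3 of 46 rose, 3 fell, median 0.10, camera adjusted p = 0.42). The peroxiredoxin prdx1 (ENSDARG00000025350, -0.57 ± 0.10) and the glutathione transferase gstt1a (-0.59 ± 0.15) fell, while gstm3 (ENSDARG00000088116, 0.92 ± 0.17) and the sulfiredoxin srxn1 (0.68 ± 0.16) rose. The glutathione peroxidase gpx1a (-0.07 ± 0.11), the glutathione synthesis gene gclc (-0.01 ± 0.14) and the haem oxygenase hmox1 (0.54 ± 0.31) did not pass the edgeR quasi-likelihood test, with Benjamini-Hochberg adjusted p = 0.728, 0.977 and 0.265. Among the other selenoproteins 4 of 29 rose and 1 fell (camera adjusted p = 0.13). selenon (1.39 ± 0.18), selenom (0.94 ± 0.22) and selenow2b (0.61 ± 0.18) rose, and the deiodinase dio1 fell by 0.85 ± 0.15. In the list of selenium incorporation machinery 2 of 9 fell (camera adjusted p = 0.684), one of them the endocytic receptor lrp2b (-1.32 ± 0.27). Without wild type replicate 3 the antioxidant list (median 0.26) and the selenoprotein list (median 0.28) passed as higher, each with camera adjusted p = 0.0277 (up to 0.955 and 0.649 over their alternatives), with 11 and 7 members higher, and hmox1 rose by 0.85 in the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0447, 0.0315 to 0.509 over its alternatives). The selenoprotein list also passed as higher without both replicate 3 libraries (median 0.22, camera adjusted p = 0.0457, 9 higher and 3 lower), and without wild type replicate 3 the Nrf2 list had 10 members higher and 4 lower. In the Nrf2 list 1 fell without mutant replicate 1, 2 or 4 or wild type replicate 1 or 2, and 1 rose without mutant replicate 4 or wild type replicate 1 or 2. Without mutant replicate 1 or 2 or wild type replicate 1, 2 or 4, 1 selenoprotein gene and 1 antioxidant gene were higher, and without mutant replicate 4, 2 selenoprotein genes were. Over the fits that left out 1 library, 2 to 5 antioxidant genes and 1 to 2 selenoprotein genes were lower. Counts adjusted over the list alone were 5 selenoprotein genes higher and 1 lower, and 2 antioxidant genes higher and 3 lower. In the selenium incorporation list 3 fell without mutant replicate 3 and 1 without any other single library. Calls of single genes were lost with 1 library left out for srxn1 (mutant replicate 4 or wild type replicate 1 or 2, edgeR quasi-likelihood Benjamini-Hochberg adjusted p 0.0503 to 0.064), gstt1a (mutant replicate 1, 2 or 4 or wild type replicate 1 or 2, 0.0615 to 0.0814), selenom (mutant replicate 1 or 2 or wild type replicate 1, 2 or 4, 0.0546 to 0.0662) and selenow2b (any except mutant replicate 3, 0.059 to 0.111).

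Ribosomal protein genes fell as a list by a small amount. Of 66 genes 15 fell, or 61 adjusted over the list alone, with a median of -0.36 and quartiles of -0.39 and -0.34 (camera adjusted p = 1.8e-09, adjusted p = 0.645 with an estimated correlation). rpl10a fell by 0.63 ± 0.13 and rps9 by 0.53 ± 0.14. The direction held under each scaling, but scaling by library size only left 3 members below the threshold and a median of -0.28, and upper-quartile factors left 9. The DESeq2 Wald test called 58. Leaving out mutant replicate 1 or 2 or wild type replicate 1, 2 or 4 left 1 member lower and leaving out mutant replicate 3 left 2, while 24 were lower without mutant replicate 4 and 58 without wild type replicate 3. The ribosome biogenesis list was not called (4 of 48 fell, median 0.04, camera adjusted p = 0.852), with the helicase ddx21 (-1.15 ± 0.30) and bysl (-0.49 ± 0.12) lower. Without mutant replicate 1 or 2 or wild type replicate 1, 2 or 4 none of its members passed in edgeR, and without wild type replicate 3, 5 were higher and 5 lower. DNA replication and cell cycle genes were not called as a list (2 of 34 fell, median -0.29, camera adjusted p = 0.11). The fallen members were the mitotic genes nusap1 (-0.95 ± 0.26) and cenpf (-1.10 ± 0.32), and cenpf stood at 38.3 CPM in wild type replicate 3 against 15.9 to 17.3 CPM in the other wild type libraries. The cell cycle list passed as lower without mutant replicate 3 (camera adjusted p = 0.0211) and without wild type replicate 1 (0.00745), 2 (0.0318) or 4 (0.0128), and with a term for the replicate 3 libraries (0.00971), with 0.00745 to 0.916 over its alternatives. In contrast, its median was 0.18 without wild type replicate 3, with 2 members higher and 2 lower, and -0.005 without both replicate 3 libraries. Counts adjusted over the list alone were 0 for both the ribosome biogenesis and the cell cycle list in edgeR. At an unadjusted p under 0.05, 9 ribosome biogenesis genes were lower and 3 higher and 5 cell cycle genes lower, and the DESeq2 Wald test, adjusted over all genes, called 6 and 5 lower. With library size only, nusap1 and cenpf lost their calls (edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.059 and 0.0649, 0.000844 to 0.0992 and 0.00101 to 0.114 over their alternatives). Calls of single genes were lost with 1 library left out for rps9 and ddx21 (any except mutant replicate 4 and wild type replicate 3, edgeR quasi-likelihood Benjamini-Hochberg adjusted p 0.0528 to 0.082 and 0.0609 to 0.0849), bysl (mutant replicate 1 or 2 or wild type replicate 1, 2 or 4, 0.0584 to 0.0866), nusap1 (mutant replicate 1, 2 or 4 or wild type replicate 2, 0.0814 to 0.0992) and cenpf (any except mutant replicate 3 and wild type replicate 3, 0.0546 to 0.114).

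Smaller list changes were spread over several tissues. Of 37 epidermis and keratinocyte genes 11 rose and 3 fell (camera adjusted p = 0.0059, adjusted p = 0.564 with an estimated correlation), led by the claudin gene cldni (1.07 ± 0.10) and epcam (0.83 ± 0.12). Of 25 cardiac muscle genes 5 rose (camera adjusted p = 0.0175, adjusted p = 0.504 with an estimated correlation), with tnni1 (ENSDARG00000052708, 0.99 ± 0.15) and myl7 (0.58 ± 0.16). Of 19 erythroid genes 4 fell, including the anion exchanger slc4a1 (ENSDARG00000012881, -1.96 ± 0.42), and of 36 circadian clock genes 5 fell, including rora (-0.58 ± 0.10) and rorab (-0.84 ± 0.15). Their camera adjusted p values were 0.019 and 0.0151, with adjusted p = 0.649 and 0.313 with an estimated correlation. Without wild type replicate 3 the epidermis, erythroid and cardiac lists lost their calls (camera adjusted p = 0.146, 0.158 and 0.0555), as did the erythroid list without mutant replicate 4 (0.0558), the cardiac list without mutant replicate 1 (0.0612), and the epidermis and erythroid lists without both replicate 3 libraries (0.0663 and 0.164). Over their alternatives these p values ran from 0.000146 to 0.564 for epidermis, 0.000138 to 0.649 for erythroid and 0.0061 to 0.504 for cardiac genes. The 5 higher cardiac genes became 1 without mutant replicate 1 or wild type replicate 1, 2 without mutant replicate 2 or wild type replicate 2 or 4, and 3 without mutant replicate 4. The 5 lower clock genes became 2 without mutant replicate 1 or 4 or wild type replicate 1 or 2, 3 without wild type replicate 4 and 9 without wild type replicate 3. Without both replicate 3 libraries 19 were lower, with a term for them 17 and with 1 surrogate variable 19, and limma-voom with quality weights called 13 lower. For these lists 3 clock genes fell, 6 cardiac genes rose and 1 fell, and 12 epidermis genes rose and 4 fell adjusted over the list alone. Without wild type replicate 4, 7 erythroid genes were lower, and without wild type replicate 3, 7 epidermis genes were, against 1 without mutant replicate 2 or wild type replicate 1 or 2. myl7 lost its call with any 1 library left out except mutant replicate 3 (edgeR quasi-likelihood Benjamini-Hochberg adjusted p 0.0576 to 0.112).

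The remaining lists were not called in the test with genotype as the only term. Hypoxia genes went both ways, with 5 of 24 rising and 5 falling (camera adjusted p = 0.814). ndrg1 (ENSDARG00000010420) fell by 2.84 ± 0.30 and the oxygen sensor egln3 rose by 1.47 ± 0.32. The hypoxia counts moved to 3 higher and 2 lower without mutant replicate 1, 2 and 3 without mutant replicate 2, 6 and 3 without mutant replicate 3, 3 and 4 without mutant replicate 4, 2 and 2 without wild type replicate 1 or 2, 5 and 8 without wild type replicate 3 and 4 and 3 without wild type replicate 4. In glycolysis 3 of 27 fell (camera adjusted p = 0.768), with 0 falling in edgeR without mutant replicate 1 or wild type replicate 1 or 2, 1 without mutant replicate 4 or wild type replicate 4, and 5 (3 rose) without wild type replicate 3. Adjusted over the list alone 0 glycolysis genes passed in edgeR, against 4 lower and 2 higher at an unadjusted p under 0.05 and 4 lower and 2 higher by the DESeq2 Wald test over all genes, while 5 hypoxia genes rose and 7 fell and 3 skeletal muscle genes rose and 3 fell. The lists of ionocytes and kidney (6 of 37 rose, 1 fell, camera adjusted p = 0.0768), cartilage, bone and notochord (3 of 33 rose, 1 fell, 0.161), skeletal muscle (3 of 57 rose, 4 fell, 0.159), fatty acid synthesis (1 of 20 rose, 1 fell, 0.641) and cholesterol synthesis (1 of 20 rose, 0.746) were not called either. For skeletal muscle, scaling by library size only gave 11 higher and 3 lower and the DESeq2 Wald test 11 and 4. There 1 was lower without mutant replicate 1 or 2 or wild type replicate 1 or 2, and 2 without mutant replicate 4. For ionocytes and kidney 3 rose without mutant replicate 1, 1 without wild type replicate 1 and 2 without wild type replicate 2, and for cartilage 0 rose in edgeR without wild type replicate 1 or 2, 1 without mutant replicate 2 or wild type replicate 4, and 7 without wild type replicate 3. In edgeR no member passed among 47 nuclear genes of oxidative phosphorylation (camera adjusted p = 0.298), where cox8a had the smallest p (0.37 ± 0.15). There 1 gene was higher at an unadjusted p under 0.05, while the DESeq2 Wald test called 0 and limma-voom with quality weights called 10, all higher. Nor did any of 17 glucocorticoid response genes pass (camera adjusted p = 0.814), where tat had a log2 fold change of -1.37 ± 0.43. At an unadjusted p under 0.05 1 was higher and 2 lower, the DESeq2 Wald test called 2 lower, and limma-voom called 1 higher and 3 lower. Without wild type replicate 3 the oxidative phosphorylation (median 0.20) and cholesterol synthesis lists (0.72) passed as higher, each with camera adjusted p = 0.0126 (up to 0.96 and 0.995 over their alternatives), with 4 and 5 members higher. Other lists that passed as higher with 1 library left out were cartilage, bone and notochord (mutant replicate 4, 0.0404, up to 0.854 over its alternatives), ionocytes and kidney (mutant replicate 3, 0.0373, and wild type replicate 4, 0.0128, up to 0.545) and skeletal muscle (wild type replicate 2, 0.0491, up to 0.854). By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, cox8a passed without wild type replicate 3 (adjusted p = 0.0133, 0.00784 to 0.294 over its alternatives), and tat passed without it (0.0154) and without mutant replicate 4 (0.0302, 0.00235 to 0.148 over its alternatives).

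Called genes were not concentrated on the chromosome of *selenoh*. There, 116 of 643 tested genes were called, 18%, against 19.6% elsewhere (odds ratio 0.902, 95% interval 0.728 to 1.11, Fisher's exact test, two-sided p = 0.359). Among the 50 nearest tested genes 10 were called (odds ratio 1.03, exact p = 0.86).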

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

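In this part only the count of sample splits was planned, and all other tests were chosen after the results were seen. Across 200 groups of 4 values, 15 had 1 library far from the other 3, where chance flags about 1 in 20, or 10. Of these, 10 lay in replicate 3 libraries, 6 in wild type and 4 in the mutant.

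The split of the samples by genotype called 4626 genes, and 1 of the 35 splits into 4 and 4, the real one, gave as many. The highest of the others called 5. A share of 1 in 35 is the smallest that this count can give. Every other split mixes the genotypes, which adds the genotype difference to the spread within its sides. Chance is therefore not excluded, and neither is another difference between the groups.

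Both replicate 3 libraries lay far from their groups on the second principal component, at -71 in wild type (others 17.2 to 27.4) and -59.6 in the mutant (others 15.7 to 25.8). Depth and a swap of labels are argued against, because wild type replicate 3 held 53865807 counts, inside the 51246749 to 56409917 of the other 6 libraries, and 1225 *selenoh* counts. Circadian clock genes deviated by a median of 1.16 on the log2 scale in these libraries, more than in 100% of 10000 expression-matched random lists. Of them, 33 of 36 (91.7%) deviated in the same sense in both, against 69.1% of all genes. The random lists had a 95th percentile of 0.331. Cholesterol synthesis (1.15, 100% in the same sense), glucocorticoid response (1.06, 88.2%) and cell cycle genes (0.93, 94.1%) lay above it too. So did many other lists, from inflammation (0.805) down to glycolysis (0.339). The random lists were drawn gene by gene, so lists whose genes vary together can exceed them easily. The test therefore does not single out time of day or light. The period gene per1 deviated by -3.71 in the mutant library and -4.32 in the wild type one for ENSDARG00000056885, and by -1.19 and -1.81 for its other ID, ENSDARG00000012499, and the light-induced per2 by 3.05 and 3.42. Collection at another time of day or under other light may account for part of this, as a hypothesis found and tested on the same data. A shared preparation day stays open because the labels name none.

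The fall of the exocrine pancreas genes was weighed as a second pattern. Scaling could not produce it: the median stayed at -6.94 with library size only, the scaling that moved it closest to 0. Near-complete loss of the digestive organs as a whole is argued against by the hepatocyte list, whose lower quartile was -0.94. A smaller reduction of other digestive organs was not tested. In the intestine list 12 of 31 genes fell and 3 rose (median -0.485). Fewer exocrine cells and lower transcription per cell both remain candidate explanations that bulk RNA does not separate, and genotype differs between the groups by design.

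*selenoh* in mutant replicate 2 stood at 0.358 CPM against 0 to 0.0181 CPM in the other mutant libraries, 2.18% of the wild type mean (exact 95% interval 1.33% to 3.37%). The first test took the median of 23 exocrine genes in that library, 1.8% of their lowest wild type library, which is above 1.33% and on the side of a wild type larva in the sample. The other mutant libraries reached 0.902% to 1.65% with at most 1 *selenoh* count, so that median does not decide, and a wild type larva cannot be told apart from exocrine counts of the mutant itself. A further test was added after that result, since carried-over RNA or reads would bring each gene at its share: 7 of the 23 genes, among them c6ast4 (0.39%) and amy2a (0.56%), lay below 1.33% with their whole counting interval, which argues against carryover from these wild type libraries. A wild type larva with little exocrine tissue, or residual mutant transcript, may still be the source.

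Other single libraries far from their group were, in CPM, wild type replicate 4 for lepb (3.31, others 0 to 0.459), mdm2 (33.9, others 29.2 to 30), gstt1a (40.2, others 54.4 to 55.2) and il7r (1.2, others 0.798 to 0.86). Wild type replicate 3 was low for amy2a (453, others 642 to 671), ddx21 (183, others 442 to 464) and epcam (150, others 189 to 196), and high for cenpf (38.3, others 15.9 to 17.3) and pdia4 (36.8, others 23.7 to 25.7). Mutant replicate 3 was high for c6ast3 (0.408, others 0.0732 to 0.108) and low for phlda3 (22.1, others 27.9 to 29.1) and hsp90b1 (169, others 299 to 312).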

How the results depend on the processing

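Leaving out both replicate 3 libraries, a term for them, TMM without the exocrine list and removal of identical genes were chosen after seeing the data. Under DESeq2 size factors, upper-quartile factors, library size only, the DESeq2 Wald test, both expression filters, TMM without the exocrine list and removal of identical genes, the counts stayed within 1.5 times 2339 higher and 2287 lower. limma-voom with quality weights gave 5039 higher and 4765 lower, 1 surrogate variable 4093 and 4020, the term for the replicate 3 libraries 3975 and 3950, and leaving both out 4200 and 3956. An adjusted p under 0.01 gave 955 and 915, and the 2-fold limit 718 and 816, by construction. Leaving out 1 library gave 1262 to 3667 higher and 1235 to 3374 lower. For the other changes the cause was not tested. Of the 4626 calls, between 2483 (without wild type replicate 2) and 4626 were shared with each alternative that refitted the model, and 0 turned direction there.

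The replicate block gave 3783 higher and 3623 lower, and brought list calls for cell cycle (camera adjusted p = 0.00964), cartilage and ionocyte genes (0.0418 each), with 18 clock genes lower. The labels do not say that equal numbers mark pairs, so the numbers were not taken as pairs. Same-numbered libraries correlated at 0.095, 0.066, 0.46 and 0.237 after removing group means. Mutant replicates 1, 3 and 4 correlated best with the wild type library of their own number. Mutant replicate 2 correlated best with wild type replicate 1, at 0.124. Handling shared by libraries of equal number is therefore not excluded.

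The 17 called lists became 2 with an estimated correlation and stayed between 16 and 20 otherwise. *selenoh* stayed at or below 0.724% of wild type with 1 library left out (lowest 0.0348%, without mutant replicate 2). Without both replicate 3 libraries it was 0.799% with an exact permutation p of 0.1, the smallest that 3 against 3 can give. The odds ratio for its chromosome was 0.822 and 0.936 under its alternatives. Of 96 named genes, 90 were called, 79 kept the call under every alternative run, 11 lost it at least once and 0 of the calls reversed. The uncalled gclc (log2 fold change -0.126 to 0.068) and gpx1a (-0.148 to 0.005) changed sign over the alternatives. cdkn1a passed under 4 alternatives, with adjusted p from 0.00288 to 0.369 over all of them. Depth of 51246749 to 56409917 counts means that a count of 0 does not exclude levels up to about 0.059 CPM. The edgeR simulation recovered 1 of 67 genes changed 1.5-fold. It held fewer changed genes than the data, with 97 calls against 4626, so it can understate recovery here.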

Other observations

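All lists and tests in this part were chosen after the data were seen, and each list was picked because some of its members had been noticed. The list p values are therefore descriptive. They are adjusted over only 5 lists and cannot be set against those adjusted over the 38 lists fixed beforehand. Transcription factors of the developing retina were lower in the mutant. Of 32 measured, 28 fell and 1 rose in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (median -1.34, camera adjusted p = 1.08e-35 over 5 lists, adjusted p = 0.0222 with an estimated correlation). atoh7, needed for retinal ganglion cells, fell by 4.06 ± 0.34 on the log2 scale, six7 by 3.27 ± 0.39, foxn4 by 3.18 ± 0.20 and the rod factor nr2e3 by 2.78 ± 0.38. The exception was prdm1 (0.77 ± 0.11). Its members pax6 (ENSDARG00000045936) and neurod1 also belong to the endocrine pancreas and gut hormone list.

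Complement genes were higher: 12 of 24 rose (median 0.49, camera adjusted p = 1.46e-08, adjusted p = 0.116 with an estimated correlation), with c7a at 2.42 ± 0.19 and c6.2 at 2.06 ± 0.21. Without mutant replicate 1 or wild type replicate 1, 7 complement genes rose. The complement gene c4b also belongs to the inflammation list, so the results of these lists are not independent. Of 12 NADPH oxidase genes 6 rose (camera adjusted p = 0.000644, adjusted p = 0.116 with an estimated correlation), including cyba (1.46 ± 0.16) and noxo1a (2.45 ± 0.42). Proteasome genes shared a small shift (median 0.41, camera adjusted p = 1.77e-05, adjusted p = 0.48 with an estimated correlation), although 0 of 31 passed singly in the main edgeR fit. Of these 31, 17 were higher at an unadjusted p under 0.05, the DESeq2 Wald test called 2, and limma-voom with quality weights called all 31, each higher, as did edgeR without wild type replicate 3. With a replicate block edgeR called 29 higher, with 1 surrogate variable or a term for the replicate 3 libraries 30, and without both of these libraries 31. None passed in edgeR with any other single library left out. Of 17 aminoacyl-tRNA synthetase genes 1 rose, qars1 (0.70 ± 0.16), and the list was not called (camera adjusted p = 0.244). Without wild type replicate 3, 4 of them rose and 1 fell, 2 rose without wild type replicate 4, and none passed in edgeR without mutant replicate 2 or wild type replicate 1 or 2.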
